A study of Bos taurus with 45 samples.

How the data were processed

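Reduced representation bisulfite sequencing enriches CpG-rich fragments and reads cytosine methylation from the bases left after bisulfite treatment. It was applied to liver, mammary parenchyma and mammary fat pad of dairy calves on control, restricted and unlimited feeding, 45 libraries in all. Per the labels' protocols, libraries were made with the Ovation RRBS Methyl-Seq kit and sequenced as single reads on a NextSeq550. The submitters' processing notes name FastQC, BSMAP 2.9.0, methylKit and the build ARS-UCD1.2, with no parameters. The deposited tables list CpG cytosines of each strand separately, with counts of reads showing C and of reads showing C or T, counts of G and of G or A on the opposite strand, and an estimated count of C or T reads lowered where opposite-strand reads show A. The deposited methylation ratio is a fraction from 0 to 1, and it equalled the count of C reads divided by the estimated count, limited to 1, within 0.0039 in every library. Each listed cytosine had at least 5 reads, so cytosines below that depth were not analysed here, and the deposited counts of C or T reads reach a ceiling of 65535.

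Tissue was taken from the tissue characteristic, diet from the diet characteristic and the calf number from the title. The source names have parenchyma and fat pad exchanged in every mammary library but the fat pad one of calf 4, whose title also differs, so the count of tissue differences was also made without that library. Titles of mammary libraries follow several patterns. Those of control calves 1 and 2 have PAR where the characteristic is parenchyma and PAD where it is fat pad, and the parenchyma titles of unlimited calves 3 and 6 differ from the rest as well. The data cannot tell a complete exchange of the names from none, so each direction between parenchyma and fat pad rests on the characteristic. The labels name no separate cultures or repeats beyond the calf number. No 2 libraries of a group were alike within sampling noise, since the closest pair differed by 1.49 times the root mean square expected from read sampling. Reads are not independent molecules, so this ratio cannot show that 2 libraries come from separate samples.

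A calf number pairs samples of the same animal. Genotypes were read at 348 cytosines from the share of G among at least 8 opposite-strand reads (variant at 0.15 or less, heterozygous from 0.3 to 0.7, reference from 0.85). The 40 pairs of libraries with the same number shared a median of 91.9% of genotypes (lowest 80.3%), against a median of 61.1% (highest 90.6%) for pairs of other numbers from different tissues, and 43 of 44 libraries matched their own number best. Over the 408 most variable tiles, deviations from the tissue means correlated with a median of 0.50 (lowest 0.1575) for the same number and -0.0415 (highest 0.593) for other numbers, and 41 of 44 libraries matched their own number best. The ranges overlapped, so single pairs were not proof of identity. As the main design fixed it, tissues were compared without the calf as a block, and the blocked fit was an alternative.

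Cytosines on chromosomes 1 to 29 and X were used when at least 10 reads covered them, and the top 1 in 1000 of coverage in each library was left out. Unplaced contigs, which held 58.6% to 73.3% of the reads, were left out of tests because their copies cannot be told apart, and mitochondrial cytosines were described apart. A cytosine entered a fit when at least 3 libraries of every group covered it, and a tile of 1000 bp needed at least 3 cytosines. In a fit that left a group fewer than 3 libraries, all of that group had to cover it. Methylated and total counts were summed per tile and library. The main test was a quasi-binomial model with pooled proportions per group. The Pearson overdispersion of each tile was moderated by empirical Bayes as in limma's squeezeVar and kept at 1 or above. An F-test was then made with Benjamini-Hochberg adjustment. A tile was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. Tissues were compared in 1 fit of all libraries, and diets in 1 fit per tissue. The diet by tissue interaction was tested with limma on M-values, log2 of methylated plus 1 over unmethylated plus 1, with 9 group means and an adjusted p under 0.05. Mean methylation was the unweighted mean over cytosines with 10 reads in all libraries of a fit. It was compared with two-sided permutation tests, exact for diets and with 100000 resamples for tissues. Separation by diet was a pseudo-F on squared differences over tiles present in every library, with 10000 permutations. P-values of diet contrasts rest on the spread between these calves, which the tile tests pooled over all groups in the fit, also those not compared. The main tissue and interaction tests had no calf block and so treated libraries of the same calf as independent.

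Named tiles followed a rule fixed before the data were examined, as were the groups, the tests and most other settings. For a tissue contrast the 6 called tiles with the largest difference in each direction qualified, for a diet contrast 4 in each direction, and where fewer than 3 tiles were called, the 3 with the smallest p, given as not passing. This gave 73 names for 62 different tiles, of which the text gives examples. Gene list tests were planned but not run, and no gene names are given, since an annotation of the build ARS-UCD1.2 was not used here. The given gene table is of another assembly, so its coordinates were not used.

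The opposite-strand share of a library is the percentage of its listed cytosines with at least 5 reads on the opposite strand. Depth set the precision. A library listed 861556 to 2921238 cytosines, of which 36.1% to 48.7% had at least 10 reads. The median reads per tile and library were 100 in liver, 104 in parenchyma and 102 in fat pad, and Wilson intervals at 95% cover counting error only, because reads without molecular identifiers are not independent molecules. The quasi-binomial tests were checked on simulated data in which 200 tiles with the real reads, levels and overdispersion received a known difference. In parenchyma, for unlimited minus control, 30.5% of tiles changed by 15 points, 65.5% of those changed by 25 and 87.5% of those changed by 40 were recovered, with 2 to 8 false calls among 40733 tiles. For restricted minus control, with 4 libraries in each group, these were 17.5%, 58.0% and 88.5%, with 0 to 7 false calls. For parenchyma minus fat pad, 91.5% of tiles changed by 15 points were recovered among 37631 tiles. The limma interaction was checked otherwise, on normal noise with the residual SD of each tile and no simulated reads or levels. For parenchyma against fat pad, 38% of tiles changed by 2 M units in unlimited parenchyma and 96% of those changed by 4 were recovered. In both checks, quasi-binomial and limma, the simulated spread of a tile was alike in all groups. The recovered shares and false calls therefore do not cover an uneven spread between groups.

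Other settings chosen before the data were seen were minimums of 5 and 20 reads, no upper limit on coverage, tiles of 500 bp, cytosines covered in every library, limma on M-values with and without the calf block or diet, a rule without overdispersion at an adjusted p under 0.01 and 25 points, other minimum differences, autosomes only, single cytosines, only the 2 compared diets, leaving out cytosines with calf-specific levels, and leaving out each library in turn in the diet contrasts within a tissue. Calf-specific cytosines were defined without diet labels, by means of calves ranging over at least 40 points while the median range within a calf was at most 20 points. Analyses were run with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.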

Results

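Cytosine methylation at CpG sites was measured by reduced representation bisulfite sequencing in tissues of dairy calves (Bos taurus) raised on 3 levels of feeding. Control calves received standard nutrition, restricted calves a reduced daily amount of milk replacer, and unlimited calves milk replacer ad libitum. The tissues were liver, mammary parenchyma (the part of the young gland that holds the epithelial ducts) and the mammary fat pad, the adipose tissue into which the ducts grow. There were 45 libraries from 17 calf numbers. Liver had 4 control, 6 restricted and 5 unlimited libraries, parenchyma 4, 4 and 6, and fat pad 4, 6 and 6. A library held 58960897 to 121782579 reads at CpG cytosines in liver, 32252572 to 116271938 in parenchyma and 68599238 to 118005820 in fat pad, with a median of 8 to 9 reads per cytosine. Counts were summed over tiles of 1000 bp. A liver tile with the median of 100 reads, 50 of them methylated, had a 95% Wilson interval of 40.4% to 59.6%, which covers counting error only. Coordinates are those of the build ARS-UCD1.2, and tiles are named by position because no gene annotation of that build was used here. Which mammary tissue is called parenchyma and which fat pad rests on the tissue characteristic of the labels, whose source names have them exchanged.

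The first comparison asked how the 3 tissues differed. Liver stood apart from both mammary tissues. Of 37631 tiles, 4635 were higher and 2063 lower in liver than in fat pad, and 4233 were higher and 2272 lower in liver than in parenchyma, each with an adjusted p under 0.05 in the moderated quasi-binomial test and a difference of at least 10 percentage points. The largest difference lay on chromosome 29 from 25707001 to 25708000, at 94.6% ± 2.46 (SD, n = 15) in liver and 20.1% ± 6.18 (n = 16) in fat pad. A tile on chromosome 12 from 35757001 to 35758000 was at 88.8% ± 4.73 (n = 15) in liver, 27.6% ± 16.8 (n = 14) in parenchyma and 17.4% ± 5.76 (n = 16) in fat pad. In the opposite direction, a tile on chromosome 17 from 60107001 to 60108000 was at 5.63% ± 3.46 (n = 14) in liver, 66.9% ± 13.9 (n = 14) in parenchyma and 77.7% ± 8.04 (n = 16) in fat pad. On chromosome 2, the tile from 20765001 to 20766000 was at 5.79% ± 1.91 (n = 15) in liver and 77.2% ± 5.97 (n = 16) in fat pad. On chromosome 13, the tile from 69934001 to 69935000 was at 23.4% ± 7.59 (n = 15) in liver and 91.2% ± 6.00 (n = 14) in parenchyma. Adjusted p ranged from 1.76e-29 to 1.02e-19 over these contrasts. The balance against parenchyma differed by diet. Fitted alone, control calves had 1156 tiles higher and 2183 lower in liver than in parenchyma, restricted calves 6114 and 2583, and unlimited calves 9837 and 3993. These fits were chosen after the data were seen. They tested different numbers of tiles with different numbers of libraries, so the counts cannot be compared between diets. The longest run of neighbouring called tiles was 4. How often neighbouring tiles were both tested was not counted, so short runs do not show that the differences were scattered.

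**Figure D1:**
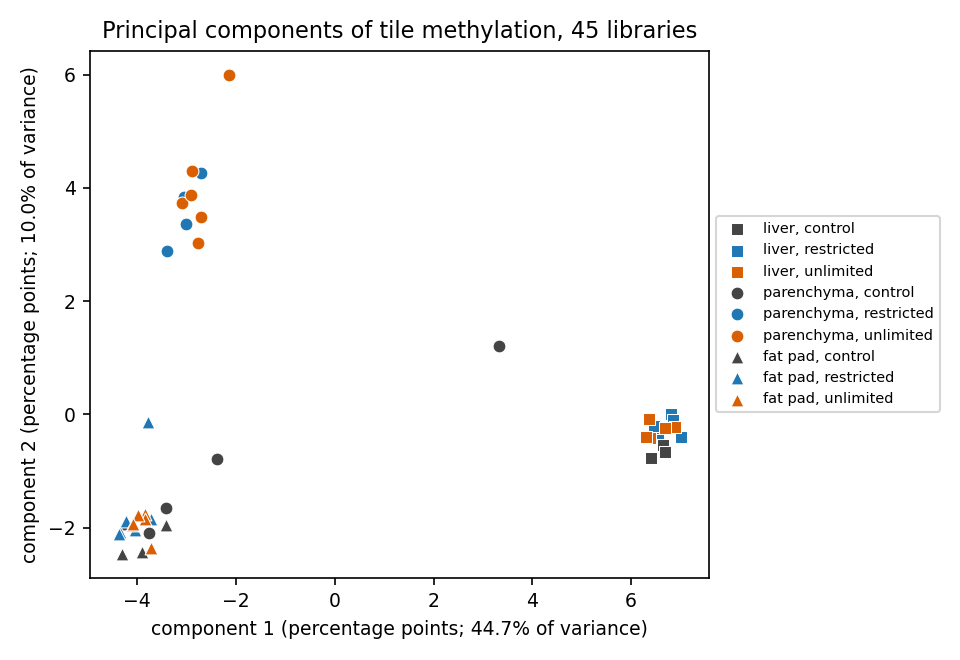
Scores of the 45 libraries on the first and second principal components of tile methylation, in percentage points, with the tissue as the marker and the diet as the colour. Component 1 carried 44.7% of the variance and separated liver from the mammary libraries, while component 2 carried 9.98% and separated most parenchyma libraries from fat pad. The control parenchyma library of calf 18 lay at 3.33 on component 1, between liver and the rest.

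Within the mammary gland, 1642 tiles were higher and 894 lower in parenchyma than in fat pad. The largest difference was on chromosome 4 from 68072001 to 68073000, at 69.4% ± 11.4 (SD, n = 12) in parenchyma and 23.1% ± 8.35 (n = 16) in fat pad. A tile on chromosome 8 from 110325001 to 110326000 was at 56.4% ± 13.8 (n = 14) and 22.6% ± 6.86 (n = 16), and one on chromosome 25 from 33431001 to 33432000 at 59.1% ± 16.6 (n = 14) and 22.6% ± 8.24 (n = 16). Lower in parenchyma were a tile on chromosome 22 from 4547001 to 4548000, at 55.7% ± 20.6 (n = 13) against 87.5% ± 3.74 (n = 16), and one on chromosome 18 from 13340001 to 13341000, at 48.8% ± 21.7 (n = 14) against 79.0% ± 3.99 (n = 16). The SD of parenchyma exceeded that of fat pad at each of these 5 tiles. Fitted alone, the 4 libraries per mammary tissue of control calves gave 0 tiles in the quasi-binomial test, of 42823 tested (4047 at an unadjusted p under 0.05). Restricted calves, with 4 parenchyma and 6 fat pad libraries, gave 2107 of 53064 tiles (1018 higher and 1089 lower in parenchyma), and unlimited calves, with 6 of each, gave 5436 of 76673 (2884 and 2552). Both diets fitted together gave 2449 higher and 2150 lower tiles, so the excess of higher tiles was smaller without control calves. These fits by diet were chosen after the data were seen, and limma was not run on them; the difference between diets is tested itself in the model with both factors, with 477 tiles for restricted and 940 for unlimited against control calves.

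The next comparisons asked how methylation differed with feeding level within each tissue. In parenchyma, the control libraries differed from both other diets, and the other diets did not separate from each other. With standard nutrition taken as between reduced and ad libitum milk replacer, these differences did not follow the amount fed. Of 40733 tiles, 845 were lower and 91 higher in restricted than in control calves, and 1481 were lower and 169 higher in unlimited than in control calves. A tile on chromosome 5 from 114177001 to 114178000 was at 85.2% ± 4.33 (SD, n = 3) in control, 23.4% ± 8.17 (n = 4) in restricted and 31.9% ± 4.32 (n = 5) in unlimited parenchyma, with adjusted p of 0.000482 and 0.000189 in the quasi-binomial test. On chromosome 22 from 4547001 to 4548000, control parenchyma was at 91.2% ± 3.07 (n = 3) and restricted parenchyma at 44.1% ± 5.67 (n = 4). On chromosome 12 from 75151001 to 75152000, control parenchyma was at 76.2% ± 9.10 (n = 4) and unlimited parenchyma at 23.2% ± 11.4 (n = 6). A tile on chromosome X from 138586001 to 138587000 was at 66.6% ± 14.6 (n = 3) in control, 11.4% ± 8.91 (n = 4) in restricted and 16.7% ± 3.11 (n = 4) in unlimited parenchyma. Higher than in control calves was a tile on chromosome 20 from 6451001 to 6452000, at 17.5% ± 6.49 (n = 3) in control, 56.2% ± 1.76 (n = 3) in restricted and 56.1% ± 16.8 (n = 4) in unlimited calves. A tile on chromosome 7 from 34437001 to 34438000 rose from 42.0% ± 12.2 (n = 4) in control to 76.6% ± 6.37 (n = 6) in unlimited calves, and one on chromosome 25 from 35024001 to 35025000 from 28.4% ± 7.59 (n = 4) to 63.3% ± 9.02 (n = 4) in restricted calves. Both contrasts rest on the same 4 control libraries and are not independent of each other.

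At the tiles that were lower in unlimited than in control parenchyma and tested in every tissue (1393), median levels in parenchyma were 85.3% in control, 65.8% in restricted and 62.7% in unlimited calves. At the same tiles fat pad stood at 80.1%, 79.0% and 78.9%, and liver at 82.7%, 83.5% and 83.1%. At the 162 such tiles that were higher, parenchyma stood at 41.8%, 64.8% and 66.5%. Fat pad stood there at 46.2%, 49.99% and 44.2%, and liver at 55.8%, 54.8% and 56.0%. All these tiles were chosen by the unlimited minus control difference in the same parenchyma libraries. The direction and part of the size of that difference therefore follow from the choice. Restricted levels are set against the same control libraries, and levels in liver and fat pad were not used in the choice. Across 20391 tiles, the Pearson r of the restricted minus control difference in parenchyma with the parenchyma minus fat pad difference in unlimited calves was 0.579 (tiles are not independent replicates; exact permutation p = 0.0286, adjusted over 6 relations 0.0857). For unlimited minus control against the tissue difference in restricted calves r was 0.596 (exact permutation p = 0.0286, adjusted 0.0857). The second highest absolute r over all 210 arrangements of the labels was 0.649, so the real labels did not give the highest. Neither passed after adjustment. For restricted minus control, the exact permutation p of 0.0286 is the smallest that 70 arrangements allow, and only the mirrored labels gave an absolute r as high. In liver and fat pad these r lay from 0.0201 to 0.0905.

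**Figure D2:**
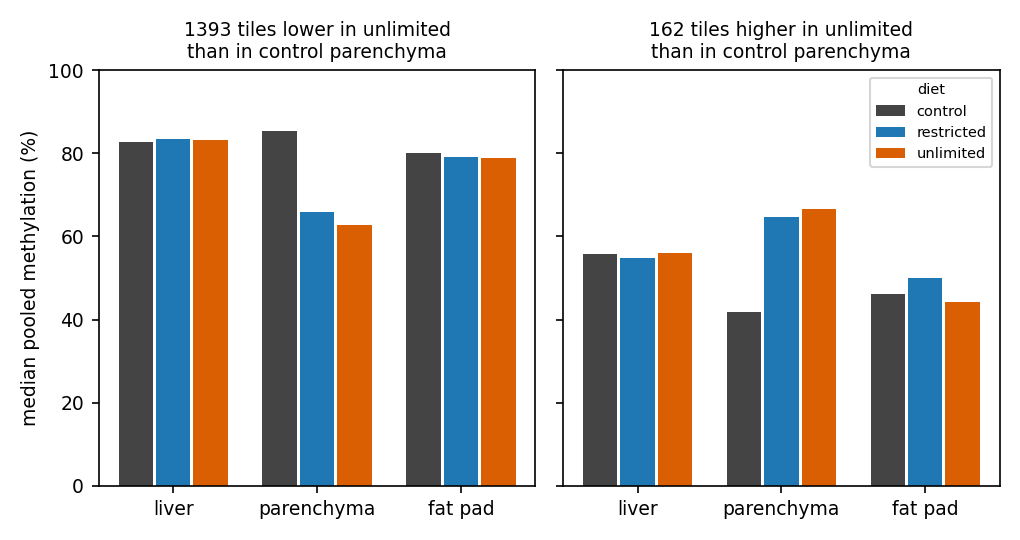
Median methylation in percent of each diet group in each tissue, from pooled reads, at the tiles lower (left) and higher (right) in unlimited than in control parenchyma and tested in every tissue. At the lower tiles the parenchyma medians were 85.3% in control and 62.7% in unlimited calves, while each fat pad and liver bar lay between 78.9% and 83.5%. The tiles were chosen by this parenchyma difference, so its direction and part of its size follow from the choice.

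Each mammary library was then placed on a scale from fat pad (0) to parenchyma (1), using 3504 tiles that differed between these tissues in restricted and unlimited calves; a library of such a calf was placed with tiles chosen without that calf. This scale was chosen after the data were seen. The control parenchyma libraries of calves 1, 2, 18 and 21 lay at 0.0878, 0.0395, 0.622 and 0.247, a mean of 0.249 ± 0.264 (SD, n = 4). Restricted parenchyma lay at 0.908 ± 0.0951 (n = 4, exact permutation p = 0.0286, the smallest that 4 against 4 allows, adjusted 0.0857). Unlimited parenchyma lay at 0.985 ± 0.130 (n = 6, exact permutation p = 0.00476, adjusted 0.0286). Restricted and unlimited calves supplied the tiles, so their parenchyma lies near 1 in part by construction, also with the placed calf left out. The p-values on this scale therefore do not test an effect of diet. With only the tiles higher in parenchyma the differences from control calves fell from 0.659 and 0.736 to 0.327 and 0.404. Neither passed 0.05 even before adjustment (unadjusted exact permutation p of 0.286 and 0.138). Control fat pad reached at most 0.0511. At the 1707 tiles that are lower in parenchyma the control parenchyma libraries lay at -0.102, -0.0673, -0.298 and -0.0768, and at the 1797 tiles that are higher they lay at 0.255, 0.131, 1.42 and 0.532. The library of calf 18 also had a score of -10.1 on the third principal component, where the next lowest of the 45 libraries was -2.81.

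**Figure D3:**
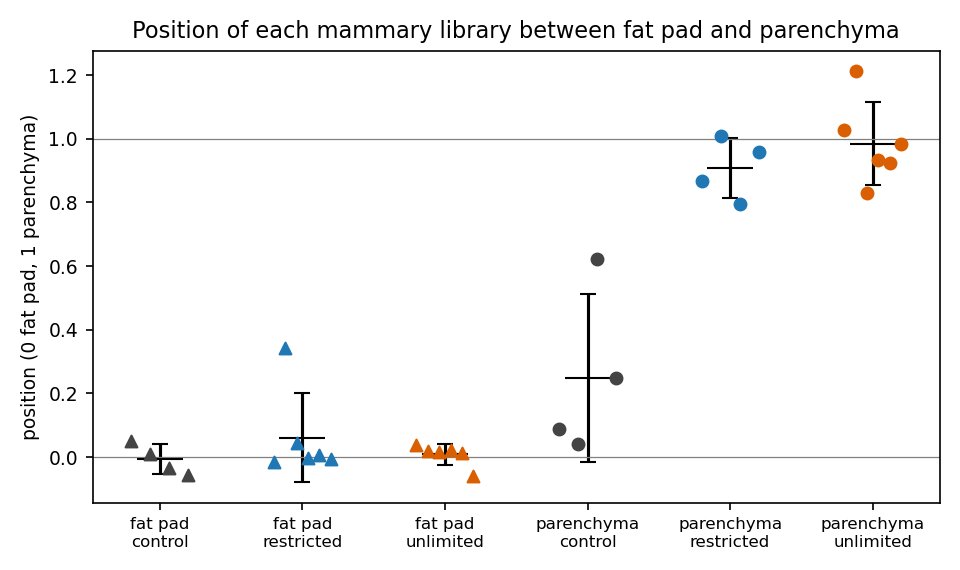
Position of each of the 30 mammary libraries between fat pad (0) and parenchyma (1), dimensionless, by tissue and diet; points are libraries, and the black bar with its whiskers is the mean ± SD. The 4 control parenchyma libraries lie from 0.0395 to 0.622, below every restricted and unlimited parenchyma library, and the fat pad library of restricted calf 5 lies at 0.344.

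The excess of lower tiles in parenchyma was smaller without 1 control library. Without the control library of calf 18, 490 lower and 160 higher tiles were called for restricted calves and 799 and 304 for unlimited calves, of 26912 tiles tested. Without those of calves 18 and 21, a choice made after the data were seen, 236 lower and 150 higher tiles were called for restricted and 521 and 333 for unlimited calves, of 30569 tested. For restricted minus control the count of 936 fell to 581 without control calf 21, and to 623, 549 and 587 without restricted calves 4, 13 and 16; for unlimited minus control the count of 1650 fell to 1050 without control calf 21. The opposite-strand share, the percentage of a library's listed cytosines with at least 5 reads on the opposite strand, split the parenchyma libraries into a group of 10 from 13.3% to 16.5% and a group of 4 above 20%; within the first group 263 and 503 tiles were called. With only the 2 compared diets in the fit, the counts were 217 and 1060. Unlimited and restricted parenchyma differed at 0 tiles in the quasi-binomial test, with 1528 at an unadjusted p under 0.05, and limma also called 0, with 1416.

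In liver and in fat pad no diet contrast gave a tile past the threshold. In liver, the tile with the smallest p between restricted and control calves, on chromosome 4 from 68899001 to 68900000, was at 30.8% ± 7.12 (SD, n = 5) and 10.8% ± 3.22 (n = 4), with an adjusted p of 0.527. On chromosome 2 from 102942001 to 102943000, unlimited liver was at 43.3% ± 15.7 (n = 4) and control liver at 87.9% ± 3.53 (n = 3), with an adjusted p of 0.659. In fat pad, a tile on chromosome 13 from 69090001 to 69091000 was at 72.6% ± 1.98 (n = 6) in unlimited and 82.6% ± 3.22 (n = 6) in restricted calves, with an adjusted p of 0.397. On chromosome 18 from 53053001 to 53054000, restricted fat pad was at 37.4% ± 8.19 (n = 4) and control fat pad at 73.9% ± 6.53 (n = 4), with an adjusted p of 0.91. None of these 4 passed the quasi-binomial test. Of 90811 liver tiles, 5666, 5542 and 4363 had an unadjusted p under 0.05 for restricted minus control, unlimited minus control and unlimited minus restricted, where the test called 0, 0 and 0; limma also called 0 in each, with 4991, 4536 and 4194. Of 64156 fat pad tiles, 3424, 4351 and 3717 had such a p and 0 were called in each contrast; limma called 0 in each, with 3729, 4392 and 3231. Without the liver library of unlimited calf 6, 1 tile was called for unlimited minus restricted. In simulated liver data, 31.5% of tiles with a difference of 15 points and 93.0% of those with 40 points were recovered for restricted minus control, so a part of such differences would have been called.

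Whether the diet contrast differed between tissues was tested itself with limma. For unlimited minus restricted, 0 of 37631 tiles passed for parenchyma against fat pad, liver against parenchyma and liver against fat pad, with 1428, 1471 and 1250 at an unadjusted p under 0.05; no other tool was run for this test. For the contrasts with control calves, added after the data were seen, parenchyma and fat pad differed at 477 tiles for restricted minus control (37 with the larger value in parenchyma) and at 940 for unlimited minus control (108). Liver and parenchyma differed at 979 and 1216 tiles, with the larger value in liver at 911 and 1130. Without the parenchyma library of control calf 18 these counts fell to 253, 623, 528 and 739, and without that of control calf 2 the 979 became 1472.

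Mean methylation over cytosines with 10 reads in every library of a tissue was highest in control parenchyma, at 72.9% ± 1.94 (SD, n = 4). Restricted parenchyma was at 70.7% ± 0.191 (n = 4, difference -2.19 points, exact permutation p = 0.0286, adjusted over 9 contrasts 0.12). Unlimited parenchyma was at 70.8% ± 0.401 (n = 6, -2.11 points, exact permutation p = 0.00476, adjusted 0.0429). The 0.0286 is the smallest p that 4 against 4 allows, so the higher adjusted p does not show a smaller difference in restricted calves. Reads pooled over all cytosines gave -1.14 points for restricted minus control and -0.854 points for unlimited minus control (adjusted exact p = 0.906 for both). For unlimited minus control a minimum of 5 reads gave -2.13 points (adjusted exact p = 0.0857). Every control library lay above every restricted and unlimited library. Control calf 18 had 75.7%, and without it the differences were -1.24 and -1.16 points. The parenchyma libraries of control calves 18 and 21 also had the highest share of mitochondrial reads listed as methylated, 0.884% and 0.701% against at most 0.614% in the other 43 libraries, and the smallest mitochondrial shares of reads, 0.0562% and 0.0762%. The parenchyma library of control calf 1 lay apart the other way, with a mitochondrial share of 0.290% of reads against at most 0.164% in the other 13 parenchyma libraries (fat pad 0.205% to 1.66%) and the lowest methylated share among them, 0.384%. On unplaced contigs the library of calf 18 had the highest mean methylation of all, 81.1%. With any 1 of the 10 libraries left out, the exact p for unlimited calves was the smallest that the remaining arrangements allow (0.00794 of 126 or 0.0119 of 84), so adjusted p of 0.0714 and 0.107 followed from the number of libraries; the difference ranged from -2.60 to -1.16 points. Within the parenchyma libraries with an opposite-strand share under 20% the differences were -2.62 points (exact p = 0.1, the smallest that 3 against 3 allows) and -2.53 points (exact p = 0.0286). Liver was at 69.2% ± 0.224 (n = 4), 69.8% ± 0.424 (n = 6) and 69.8% ± 0.463 (n = 5) in control, restricted and unlimited calves, with adjusted exact p of 0.12, 0.12 and 0.827 for the 3 contrasts; without restricted calf 5 the first was 0.0357. Fat pad was at 67.7% ± 0.605 (n = 4), 67.5% ± 0.496 (n = 6) and 67.2% ± 0.189 (n = 6), with adjusted exact p of 0.778, 0.12 and 0.321. Over the 132692 cytosines shared by all libraries, liver was at 71.7% ± 0.433 (n = 15), parenchyma at 71.3% ± 1.39 (n = 14) and fat pad at 70.5% ± 0.467 (n = 16). Liver exceeded fat pad by 1.13 points (adjusted permutation p = 3e-05, from the smallest p that 100000 resamples can give) and parenchyma exceeded fat pad by 0.785 points (adjusted 0.0193), while liver minus parenchyma was 0.341 points (adjusted 0.428). The control parenchyma libraries carried much of this. Without that of calf 18, parenchyma minus fat pad was 0.451 points (adjusted permutation p = 0.0504) and liver minus parenchyma 0.675 points (adjusted 0.00426). In restricted and unlimited calves alone, a choice made after the data were seen, these were 0.267 (adjusted 0.108) and 1.08 points (adjusted 4.5e-05).

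Libraries of a diet lay on average closer together than libraries of different diets in parenchyma, where pseudo-F was 2.09 (permutation p = 0.0013, adjusted 0.0039). The root mean square difference between parenchyma libraries averaged 8.14 points within a diet and 9.31 between diets, and reached 14.1 in 1 pair of the same diet. Without the control libraries, an alternative chosen after the data were seen, pseudo-F in parenchyma was 0.982 (adjusted permutation p = 0.804). The mean differences were then 7.41 points within a diet and 7.35 between diets, so the separation rested on the control libraries. With all diets, pseudo-F was 0.991 in liver (adjusted 0.522) and 1.07 in fat pad (adjusted 0.0712), and neither passed 0.05. Fat pad passed in 1 of 3 alternatives, without cytosines with calf-specific levels (pseudo-F 1.10, adjusted permutation p = 0.0202), and not on the 10% most variable tiles (1.03, adjusted 0.393) or without the control libraries (1.06, adjusted 0.389). The opposite-strand share moved with diet in fat pad, at 24.1% to 29.9% in all 4 control libraries and 15.0% to 17.3% in 4 of 6 unlimited ones, so the 1.10 was not read as an effect of diet.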

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

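Chosen only after the results were seen were the tests of position, of exchanged labels, of the identity of the liver library, of calls made without overdispersion and of other splits of the libraries, and the interactions with control calves; the test of sequence differences at the tiles called in parenchyma was written before its values were seen.

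The change from control calves differed between tissues. Parenchyma and fat pad differed at 477 tiles for restricted minus control and at 940 for unlimited minus control, and liver and parenchyma at 979 and 1216. In 50 splits that exchanged the 2 diets within each tissue, only the real one (1 of 50 in each case) gave as many. That share is the smallest that 50 splits allow and was not adjusted over the contrasts, so chance was not excluded. The highest other splits gave 447 and 729 tiles for the restricted contrasts and 35 and 24 for the unlimited ones. The first 2 values came from the 1 split that exchanged all 4 control parenchyma libraries with the 4 restricted ones and so kept the real grouping of that tissue; the highest splits that mixed it gave 32 and 4. Those splits break the tie between the tissues of a calf. In splits that exchanged whole calves and kept the group sizes, again only the real one gave as many (1 of 35 for restricted and 1 of 50 for unlimited minus control), and the highest others gave 4 and 6 tiles for 477 and 979, and 56 and 42 for 940 and 1216. Without the parenchyma library of control calf 18 the counts were 253, 623, 528 and 739, in the order 477, 940, 979 and 1216. For unlimited minus restricted, limma called 0 tiles in each pair of tissues (1428, 1471 and 1250 at an unadjusted p under 0.05), 50 of 50 splits gave at least as many, as a count of 0 fixes, and the highest other splits gave 1, 1 and 2.

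The control parenchyma libraries lay apart from those of the other diets. An exchange of labels between the control parenchyma and control fat pad libraries (calves 2, 18, 19 and 21) is argued against, because the highest of these fat pad libraries lay at only 0.051 on the scale from fat pad (0) to parenchyma (1), and so are sequence differences between the calves, since at the 1555 tiles called for unlimited minus control in parenchyma and tested in every tissue the larger of the median differences in liver and fat pad was 0.684 points, against 19.8 points in parenchyma (at most 1.765 against 20.2 at the tiles higher or lower for restricted minus control). The mean position of the 4 control libraries at tiles lower in parenchyma, -0.136, decided nothing about fat pad-like tissue, because low positions had prompted that test and the mean lay below the lowest fat pad library (-0.115), with calf 18 at -0.298. A mixture of the 2 tissues would place a library alike at the tiles higher and lower in parenchyma, and the former position exceeded the latter by 0.609 and 1.72 in calves 21 and 18, beyond the 26 fat pad and other parenchyma libraries (-0.184 to 0.311, SD 0.105), so fat pad alone is argued against there, while at 0.198 and 0.357 in calves 2 and 1 it cannot be told apart. An effect of feeding on the gland, a different stage of its growth, other tissue in the samples, their dissection, a single wrong label with no partner (calf 1 has no fat pad library, and its mitochondrial share of 0.290% lies within the fat pad range) and the quality of these libraries stay open, since they coincide with the control group. A steady change with the amount fed is not what the tiles show, if standard nutrition lies between reduced and ad libitum. Restricted and unlimited parenchyma lay on the same side of control and differed from each other at 0 tiles.

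The liver library of restricted calf 8 resembled the libraries of calf 9 in genotype. At 7 cytosines where calf 9 and the fat pad library of calf 8 differed, it had the genotype of calf 9 at 5 (71.4%; 71.429) and that of the fat pad library of calf 8 at 1, so a library of calf 9 under the wrong number cannot be told apart from calf 8 with so few cytosines. Kinship of calves 8 and 9 may contribute: the fat pad library of calf 8 shared 76.4% to 78.8% of genotypes with those of calf 9, more than 98.67% of other pairs of different numbers, whose median was 61.2%. No biological explanation was tested.

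A rule without overdispersion called 133 tiles in liver and fat pad over the 6 diet contrasts, 116 of them different, where the main test called 0 (unadjusted counts of 3424 to 5666; limma 0). Sequence differences between the calves were tested through the deviation of each calf from its diet mean in both tissues. Over the 41 tiles with at least 8 calves the median correlation was 0.416, against 0.0665 for all 56503 such tiles, which lies between the bounds set for and against this explanation. A first form of this test, limited to tiles read in all 14 calves, held too few tiles and was replaced after its value was seen. It cannot be told apart from other differences between calves that both tissues share, and no biological explanation was tested.

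The fat pad library of restricted calf 5 lay at 0.344 on the same scale, far from the other 5 of its group (-0.0168 to 0.0432). The fat pad library of unlimited calf 15 lay at -0.0581, below the other 5 of its group (0.0136 to 0.0387). Over 5 measures 42 groups were tested for a library far from the others, and chance gives about 1 in 20.

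Other splits were counted for each count of tiles. For restricted minus control in parenchyma only the real split gave 936 tiles (1 of 35, highest other 1). For unlimited minus control only the real split gave 1650 (1 of 99, highest other 6). The real counts lay far above the others. These shares are the smallest that so many splits allow and were not adjusted over the contrasts, so chance was not excluded. For the tissues only the real split gave 2536, 6505 and 6698 tiles (1 of 100 each, highest others 86, 892 and 1469). In splits that exchanged the tissues within calves and so parted as many pairs, only the real one of 50 was as large, and the highest others were 786, 4225 and 4021, where 2 of 13, 2 of 13 and 3 of 14 pairs were out of place. For the diet contrasts with 0 tiles, every split gave at least as many (100 of 100, and 99 of 99 for unlimited minus control in liver), as a count of 0 fixes. The highest others were 8, 2 and 2 in liver, 2 for unlimited minus restricted in parenchyma, and 2, 1 and 2 in fat pad, and the unadjusted and limma counts stand with the comparisons.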

How the results depend on the processing

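Chosen after the data were seen were the fits to calves of chosen diets, to parenchyma without calves 18 and 21 or 1 and 2, the tissue means without each library or without control calves, to libraries by opposite-strand share and with that share as a covariate, the interactions with control calves and their refits, every interaction refit without 1 library, and the scale of position with its use of the higher tiles only. Apart from fits that left out 1 library, 217 values kept their call, 53 counts moved by more than 1.5 times, 8 differences reversed, 3 became stronger and 6 weaker. Position differences were judged there by unadjusted exact permutation p. Restricted minus control counts among the weaker ones, although its main difference did not pass after adjustment (adjusted exact permutation p = 0.0857). Values in order are parenchyma minus fat pad, liver minus parenchyma and liver minus fat pad for tissues, and restricted and then unlimited against control for parenchyma. The gene list tests and their alternatives were not run.

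With a minimum of 5 reads the tissue counts were 6364, 17735 and 18563. With a minimum of 20 they were 804, 2083 and 2126, parenchyma gave 489 and 747, and the interactions gave 496 (unlimited minus control, parenchyma against fat pad), 615 and 642 (restricted and unlimited minus control, liver against parenchyma). With cytosines covered in every library the counts were 617 and 935 in parenchyma and 990, 2518 and 2583 for tissues. The methylKit-like rule without overdispersion gave 37, 32 and 18 tiles in liver, 538, 598 and 6 in parenchyma and 18, 18 and 10 in fat pad (restricted minus control, unlimited minus control, unlimited minus restricted), and 95, 1758 and 2171 for tissues. A difference of at least 25 points gave 297 and 450 in parenchyma and again 95, 1758 and 2171, and no minimum difference gave 5721, 14237 and 16015 for tissues. Single cytosines gave 204 for restricted minus control in parenchyma and 18411, 48089 and 51043 for tissues. With only the 2 diets compared, parenchyma gave 217 and 1060.

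Parenchyma minus fat pad gave 4599 tiles in restricted and unlimited calves, 0 in control calves (quasi-binomial test, 4047 at an unadjusted p under 0.05, limma not run) and 5436 in unlimited calves; liver minus parenchyma gave 3339 in control and 13830 in unlimited calves, and liver minus fat pad 13853 in unlimited calves. Without the parenchyma libraries of calves 18 and 21 the counts were 386 and 854 (150 and 333 of them higher), without those of calves 1 and 2, whose titles differ, 1516 and 2237, and in libraries with an opposite-strand share under 20% they were 263 and 503. The cause of these moves was not tested; the number of tiles tested and of libraries changed with the settings.

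Of the differences in mean methylation, pooled reads reversed liver unlimited minus control (-0.385 points), liver unlimited minus restricted (-0.768), fat pad restricted minus control (1.40; 1.3967), unlimited minus control (1.40; 1.4005) and unlimited minus restricted (0.0038), and liver minus parenchyma (-0.509). A minimum of 20 reads reversed liver unlimited minus restricted (-0.0087) and liver minus parenchyma (-0.0047). None of these 8 passed in the main test. Parenchyma unlimited minus control lost its call with pooled reads (-0.854, adjusted exact p = 0.906) and with a minimum of 5 reads (-2.13, adjusted exact p = 0.0857), where liver minus parenchyma gained one (0.855, adjusted permutation p = 0.033). In restricted and unlimited calves alone parenchyma minus fat pad lost its call (0.267, adjusted permutation p = 0.108) and liver minus parenchyma gained one (1.08, adjusted 4.5e-05). Pseudo-F of parenchyma without controls was 0.982, and that of fat pad without calf-specific cytosines 1.10 (adjusted permutation p = 0.0202). With the tiles higher in parenchyma only, the position differences from control were 0.327 and 0.404 (unadjusted exact permutation p of 0.286 and 0.138).

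Leaving out 1 library at a time reversed 5 differences in mean methylation, none of them past the threshold, and, as the number of libraries fixes, ended the call of parenchyma unlimited minus control in all 10 fits. It gave 549 to 953 and 1050 to 1513 tiles in parenchyma (549 without restricted calf 13, 1050 without control calf 21), 0 to 1 for unlimited minus restricted in liver and 0 to 0 elsewhere among diets. The interactions with control calves ranged over 253 to 713 and 623 to 1232 for parenchyma against fat pad and 528 to 1472 and 739 to 1608 for liver against parenchyma, lowest each time without the parenchyma library of control calf 18, and stayed at 0 for unlimited minus restricted. Mean methylation differences, as restricted minus control, unlimited minus control and unlimited minus restricted, ranged over 0.459 to 0.697, 0.474 to 0.740 and -0.0842 to 0.184 in liver. They ranged over -2.68 to -1.24, -2.60 to -1.16 and -0.0195 to 0.210 in parenchyma, and over -0.344 to 0.0937, -0.637 to -0.199 and -0.432 to -0.146 in fat pad. Parenchyma minus fat pad ranged over 0.451 to 0.879, liver minus parenchyma over 0.248 to 0.675 and liver minus fat pad over 1.076 to 1.197, the 0.451 and 0.675 without the parenchyma library of control calf 18. Named tiles passing in the main test kept their call in 366 of 387 comparisons and lost it in 21, of which 19 of 126 were in parenchyma restricted minus control and 2 of 132 in unlimited minus control. Named tiles not passing had no call to keep; 1 of their 395 comparisons passed. No sign was reversed.

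With the calf as a replicate block, limma called 2321, 6378 and 6640 tiles for the tissues. The interactions with control calves were 598 and 1116 for parenchyma against fat pad and 1204 and 1413 for liver against parenchyma, and unlimited minus restricted stayed at 0 in 3 pairs of tissues. Paired mean methylation differences were 0.775 (adjusted permutation p = 0.0355), 0.359 (0.502) and 1.13 points (0.0011), and the block changed no other call.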

Other observations

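The mitochondrial values and the position of libraries were compared only after the data were seen. In fat pad, mitochondrial reads took a larger share of the reads in unlimited than in restricted calves. The share at mitochondrial CpG cytosines was 1.03% ± 0.459 (SD, n = 6) in unlimited and 0.303% ± 0.129 (n = 6) in restricted fat pad, a difference of 1.74 on the log2 scale (exact permutation p = 0.00216, adjusted over 9 contrasts 0.0195), and all 6 unlimited libraries lay above all 6 restricted ones. Control fat pad was at 0.555% ± 0.204 (n = 4), with adjusted exact p of 0.229 against either diet. Of reads on placed chromosomes the difference was 1.77 (adjusted exact p = 0.0195). The order held on both sides of the opposite-strand share of 20%. Above it, unlimited calves 11 and 15 were at 0.869% and 1.66% against 0.205% to 0.545% in 4 restricted calves. Below it, 4 unlimited calves were at 0.577% to 1.53% against 0.246% and 0.208% in restricted calves 13 and 16.

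In liver the share was 0.396% ± 0.0769 (n = 4) in control, 0.399% ± 0.0923 (n = 6) in restricted and 0.355% ± 0.145 (n = 5) in unlimited calves, and in parenchyma 0.141% ± 0.106 (n = 4), 0.104% ± 0.0182 (n = 4) and 0.126% ± 0.0251 (n = 6). The control mean in parenchyma rests on calf 1 at 0.290%; the other 3 control libraries lay at 0.0562%, 0.0762% and 0.140%, the first 2 of them below every restricted and unlimited one. No diet contrast in these tissues passed (adjusted exact p of 0.364 or more). Whether the contrast differed between tissues was not tested. The share of mitochondrial reads listed as methylated was 0.342% ± 0.0238 in unlimited and 0.439% ± 0.0320 in restricted fat pad (n = 6 each, exact permutation p = 0.00216, adjusted 0.0195). It tended to be lower in libraries with more mitochondrial reads. Fat pad of unlimited calf 15 had 0.322% at 1959952 such reads, and that of restricted calf 16 had 0.487% at 162908. Whether the methylated share differed apart from the share of reads was not tested, so it is not counted as a separate result. In all, 4 measures were compared in this way over 9 contrasts each, and mean methylation on unplaced contigs passed in none (adjusted exact p of 0.407 or more).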
